A study of Canis lupus familiaris with 18 samples.

How the data were processed

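The series holds 18 Affymetrix Canine_2 arrays of total RNA from the right atrium (RA) and the right ventricle (RV) of dogs. In each chamber, 3 arrays came from controls, 3 from dogs with early heart failure (HF) and 3 from dogs with late HF. Heart failure was made by rapid ventricular pacing (tachypacing), for 2 weeks in the early and 5 weeks in the late group; the protocol text in the labels gives 2 to 3 and 5 to 6 weeks. The dogs were mongrels or beagles, and the breed of each animal is not given. The labels call the replicates biological but identify no animal, so the p-values measure the spread between these samples.

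The deposited values are log2 signal per probe set. The unit was read from the values: they lie on a log scale, and 2 spiked controls added at different concentrations lie about 2 units apart. The labels name MAS5 as the authors' processing tool, with no version, scale or target. The sorted values of the arrays nearly coincide, and the labels state no step that would make them so. The array medians lay between 5.65 and 5.75. No further normalization was applied.

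Of 43035 probe sets, 111 control probe sets were left out. The 40% of the remaining 42924 with the lowest mean signal were also left out, which left 25752 to test. Gene symbols came from the platform annotation in the reference: 29254 probe sets had a single symbol, 439 had several and 13231 had none. The array was designed on an older dog genome build than the reference annotation, so no coordinates are given. For each gene, the probe set with the highest mean signal stood for the gene, which gave 10988 genes tested.

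Each probe set was tested with limma 3.58.1 in R 4.3.3. A model with 1 mean for each of the 6 groups was fitted over all 18 arrays (12 residual degrees of freedom). Tests were two-sided with a trended variance prior, and p-values were adjusted by Benjamini-Hochberg over the probe sets tested. The threshold was an adjusted p of 0.05. Values are log2 fold changes with the standard error (SE) of the fit, from 3 arrays per group unless stated. The comparisons were each HF stage against control within a chamber, late against early HF within a chamber, RA against RV in controls, and the difference between the chambers in each HF effect (an interaction contrast). Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

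The tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where an alternative is said to be later. There were 21 lists of pathway genes and 12 lists of cell type or chamber markers, with 1291 genes, of which 1055 were named on the array. No member of the sex-linked list was named on the array, so 32 lists were tested. Each was tested with camera from limma, with a preset correlation between genes of 0.01, and adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry's directional p asks whether a list's genes move on balance 1 way and its mixed p whether they change in either direction, and neither compares a list with other genes. With all arrays, the atrial marker list in controls was the only call of camera that held with an estimated correlation. Over the 224 list tests, the median or mean of the members had another sign than the test in 31, none of which passed the threshold.

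Genes are named by a fixed rule. It takes up to 10 genes with the largest change in each direction among those past the threshold whose 3 arrays in each group did not overlap. With fewer than 5 such genes, it takes the 5 genes of smallest p in each direction. It also takes up to 4 members with the smallest p from each list described, and a set of heart failure and ion channel genes whatever their p. Of this set, NPPA and SLN had no probe set with their symbol alone, KCNJ2 and HCN4 fell below the signal filter, and 1 item is not reported here.

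The replicate numbers were checked as possible marks of a shared dog by correlating each array's deviation from its group mean. RA and RV arrays with the same condition and number correlated at 0.36, 0.24 and 0.42 in controls and at 0.17, 0.26 and 0.15 in early HF, but at 0.05, -0.42 and 0.15 in late HF. The numbers therefore pair the chambers in controls and early HF and do not in late HF. Conditions within a chamber were not paired by number. A fit with these pairs as a block was run for the chamber comparisons.

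The fit was tested on simulated values, drawn independently for each probe set with the fitted means and variances, with 200 probe sets changed in the RA early HF arrays. It recovered 61.2% of 1.5-fold, 95.5% of 2-fold and 98.5% of 4-fold changes, with 7 false calls among 177. In the same way a list shifted 1.5-fold was found, and 0 of 31 other lists were called. Simulated genes were independent, so this does not test the preset correlation between genes. Between any 2 arrays, at least 97.5% of values differed, so no array is a copy of another.

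The library labelled RA late 3 has ventricular levels of chamber markers. The fits therefore were repeated without it, a choice made after seeing the data. The other alternatives were quantile normalization, median-centring, other signal filters, a floor on low values, leaving out probe sets that may cross-hybridise, other variance priors, array weights, fits of the compared groups alone, replicate blocks, other thresholds, and leaving out each array in turn. The closing section gives their effect.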

Results

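The measurements were log2 signals per probe set on 18 canine arrays, in 6 groups of 3. These were RA and RV, each from controls, early HF (2 weeks of ventricular tachypacing) and late HF (5 weeks). Errors are standard errors (SE) of the limma fit with n = 3 arrays per group, unless said otherwise, and changes are log2 fold changes. As a sign of RNA quality, the 3' minus 5' signal of GAPDH averaged 1.32 (SD 0.25) in RA controls, 1.46 (SD 0.17) in RA early HF, 1.28 (SD 0.24) in RA late HF, 1.17 (SD 0.10) in RV controls, 1.24 (SD 0.17) in RV early HF and 1.36 (SD 0.10) in RV late HF. That of EF1A lay between 9.28 and 9.58 in RA controls and between 8.01 and 8.28 in RV controls, with 8.19 to 8.76 in RV early HF and 8.51 to 8.86 in RV late HF, and was 8.36 in the library labelled RA late 3, so it differed between the control chambers. Group averages under 5.31, the limit of the signal filter, lie near background, and changes against them are to be read as lower bounds. Among the genes named below these were POSTN (4.20), C6 (4.34), TOP2A (4.95), LY96 (4.81), PLPPR5 (4.75), IRX5 (5.16) and NEFL (5.18) in RA controls. They were also HSD17B13 (5.06), CAMK1D (4.90) and ABI3BP (4.99) in RV controls, SLC35F6 (5.28) in RA late HF and NEFL (4.84) in RV early HF. POSTN averaged 4.02, 4.56 and 4.88 in the RV groups.

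In controls, genes of the atrial myocyte were higher in RA: DKK3, a secreted Wnt modulator, by 5.81 (SE 0.64, adjusted p = 0.000198), and MYL4, the atrial essential light chain, by 5.22 (SE 0.85, adjusted p = 0.00317). The gap junction gene GJA5 was higher by 2.27 (SE 0.17, adjusted p = 1.12e-05), PAM, which amidates peptides, by 2.69 (SE 0.42, adjusted p = 0.00242), and MYL7, the atrial regulatory light chain, by 2.05 (SE 0.39, adjusted p = 0.00906). Further genes higher in RA were CRYM (4.23), HSD17B13 (4.04), PRSS23 (3.98), CAMK1D (3.02), HPGDS (2.85), RBP4 (2.79) and RABGAP1L (2.66). Lower in RA than in RV were MYL2, the ventricular regulatory light chain, at -6.84 (SE 0.87, adjusted p = 0.000735), MYL3, the ventricular essential light chain, at -6.24 (SE 0.89, adjusted p = 0.00134), and the transcription factor IRX5 at -2.78 (SE 0.56, adjusted p = 0.0124). The neurofilament gene NEFL was also lower (-3.52), as were PLPPR5 (-3.41), FHIT (-3.24), HSD11B1 (-3.24), UCP3 (-3.09), LOC612108 (-2.59) and PLA2G7 (-2.55). Another FHIT probe set was not lower.

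Gene lists set the chambers apart in controls. Of 13 atrial myocyte markers, 7 were higher in RA, 0 lower and 6 did not pass (7 adjusted over the list alone), with GJA5, DKK3, PAM and MYL4 in front; the list passed camera at adjusted p = 8.99e-09, and adjusted p = 0.0131 with an estimated correlation. Of 20 ventricular myocyte markers, 5 were lower and 0 higher (8 lower adjusted over the list alone), among them MYL2, MYL3, MYOZ2 (-0.60, SE 0.09) and IRX5. The ventricular list passed camera as lower at adjusted p = 3.51e-08 (adjusted p = 0.426 with an estimated correlation). In the fit without the library labelled RA late 3 the ventricular list had adjusted p = 0.0138 with an estimated correlation. Of 40 genes of fatty acid oxidation, 7 were lower in RA and 0 higher (9 lower adjusted over the list alone), such as the fatty acid transporter CD36 (-1.03, SE 0.18), MLYCD (-0.98, SE 0.19) and ETFB (-0.91, SE 0.21). The fatty acid list passed camera as lower at adjusted p = 3.53e-07 (adjusted p = 0.426 with an estimated correlation). Of 52 genes of fibrillar collagen and matrix, 3 were higher in RA and 0 lower (8 adjusted over the list alone): FBLN2 (1.84, SE 0.32), FN1 (1.59, SE 0.37) and COL14A1 (0.97, SE 0.23). The matrix list passed camera as higher at adjusted p = 1.29e-07 (adjusted p = 0.426 with an estimated correlation). Fibroblast markers were higher beside them, 3 of 20 with 0 lower (9 adjusted over the list alone), namely SMOC2 (1.02), GSN (0.85) and DPT (1.12). The fibroblast list passed camera as higher at adjusted p = 0.000176 (adjusted p = 0.426 with an estimated correlation).

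Of 50 ribosomal protein genes, none passed alone and 0 did adjusted over the list alone, but 49 had a positive difference (RPS28 0.34 (SE 0.10), RPL10A 0.40 (SE 0.12)). The ribosomal list passed camera as higher at adjusted p = 1.44e-14 (adjusted p = 0.426 with an estimated correlation). Of 19 adipocyte markers, 2 were higher in RA and 0 lower (7 higher and 2 lower adjusted over the list alone): SCD (1.41) and RBP4. The adipocyte list passed camera as higher at adjusted p = 0.000533 (adjusted p = 0.426 with an estimated correlation). Among 61 genes of oxidative phosphorylation, 0 passed, also adjusted over the list alone, with SDHD at -0.36 (SE 0.09) and CYCS at -0.31 (SE 0.09); the list was lower in RA by camera (adjusted p = 0.000176, adjusted p = 0.675 with an estimated correlation). Of 27 genes of the gap junction and intercalated disc, 3 were higher (GJA5, CXADR 0.70 and LMNA 0.49) and 0 lower (4 higher and 1 lower adjusted over the list alone). The intercalated disc list passed camera as higher at adjusted p = 0.0371 (adjusted p = 0.426 with an estimated correlation). None of 33 genes of endoplasmic reticulum and heat shock stress passed, 0 adjusted over the list alone (CALR 0.39 (SE 0.12), CANX -0.49 (SE 0.14)). The heat shock list passed camera as higher at adjusted p = 0.0313 (adjusted p = 0.675 with an estimated correlation). With control chambers paired by number the intercalated disc call ended (adjusted p = 0.0803), as it did without the library labelled RA late 3 (adjusted p = 0.0639). Single libraries ended these last calls as well. For the intercalated disc list they were RA control 2 (adjusted p = 0.0618 without it) and RV control 2 (0.094), and for the stress list RA control 2 (0.0872), RA control 3 (0.065) and RV control 2 (0.136).

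In all, 748 of 25752 probe sets differed between the chambers in controls by limma, 436 higher and 312 lower in RA. A fit of the controls alone gave 2162, array weights 2605 and leaving out probe sets that may cross-hybridise 494. With control chambers paired by number the count was 963, RBP4 no longer passed (adjusted p = 0.061) and NPPB did (adjusted p = 0.0417). It was 251 without RV control 2, 279 without RA control 3, 336 without RV control 1, 374 without RA control 2, 433 without RA control 1, 439 without RV control 3 and 1458 without the library labelled RA late 3, which enters only through the shared spread. Leaving out a single control kept 12 of the 20 genes of largest difference in every case: DKK3, MYL4, CRYM, PRSS23, CAMK1D, HPGDS, PAM, MYL2, MYL3, NEFL, FHIT and PLA2G7.

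Among the heart failure and ion channel genes, MYL2, MYL7 and GJA5 passed in controls. Natriuretic peptide B (NPPB) was 4.37 (SE 1.29, adjusted p = 0.0829), COL1A1 1.62 (SE 0.70, adjusted p = 0.256) and COL3A1 1.35 (SE 0.49, adjusted p = 0.159). The differences of KCND3 (-0.26), KCNIP2 (-0.16), KCNH2 (-0.16), KCNQ1 (0.00), KCNA5 (-0.22), CACNA1C (-0.17), GJA1 (-0.20), RYR2 (-0.14), ATP2A2 (0.01), PLN (-0.17) and SLC8A1 (-0.03) did not pass.

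The library labelled RA late 3 had the chamber markers of RV. Its signals were 14.17 for MYL2, 13.89 for MYL3 and 8.10 for IRX5, where RV controls averaged 14.15 (SD 0.02), 14.06 (SD 0.08) and 7.94 (SD 0.35) and RA controls 7.31 (SD 1.81), 7.82 (SD 0.20) and 5.16 (SD 0.12). MYL7 (11.65) and PAM (10.61) also lay at RV levels, MYL4 (11.65) and DKK3 (9.17) lay between the chambers, and GJA5 (8.74) lay near RA. On an axis from 0 at the RV control mean to 1 at the RA control mean, over 1458 probe sets that differed between control chambers, this library stood at 0.156. The other RA libraries of dogs with HF stood between 0.863 and 0.991, and RV libraries between -0.053 and 0.345. Results are therefore given with and without this library, the latter chosen after seeing the data.

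**Figure D1:**
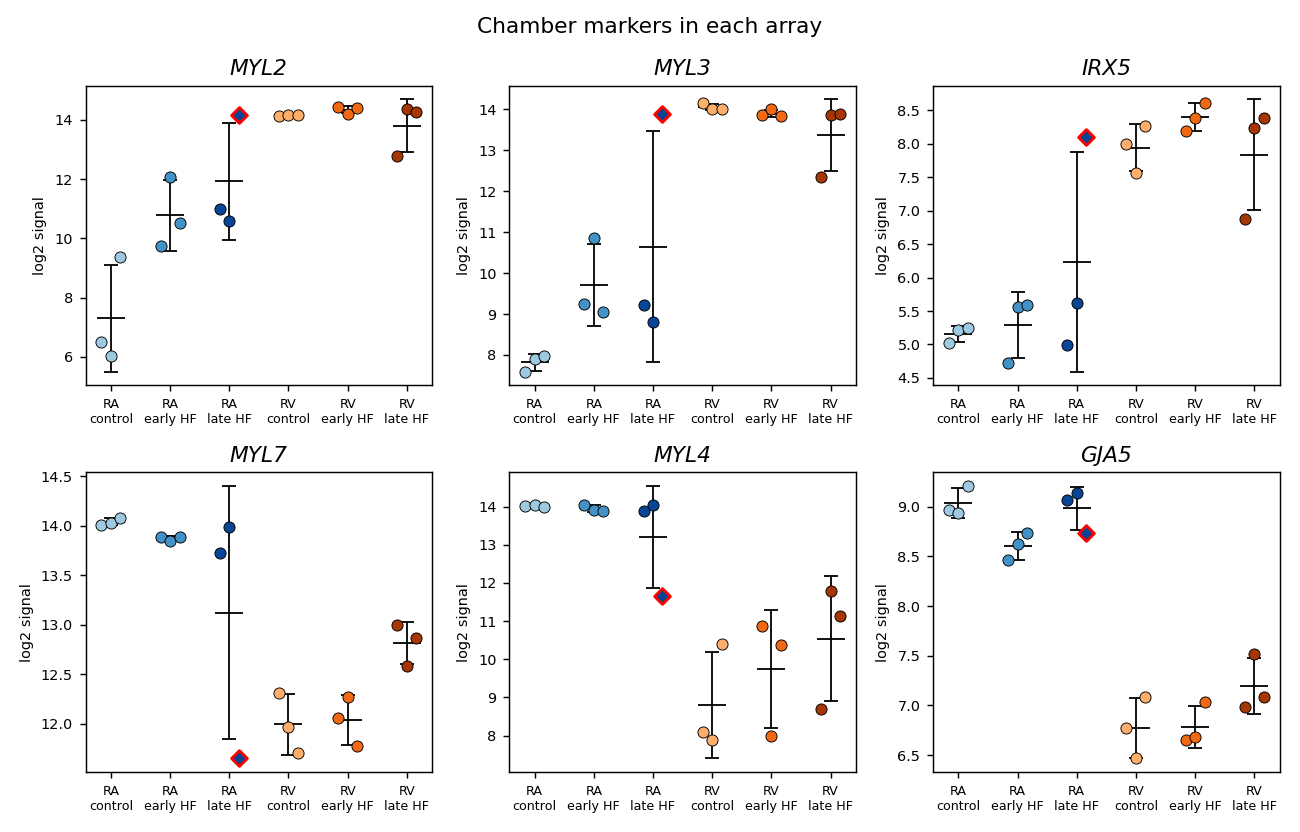
Log2 signal of chamber marker genes in each array of the 6 groups; points are arrays, bars are group means with SD (n = 3), and the diamond with a red edge is the library labelled RA late 3. Its MYL2 signal of 14.17 lies with the RV arrays.

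Early HF in the right atrium was compared with control. Genes of the extracellular matrix rose: periostin (POSTN), a matricellular protein near background in controls, by at least 4.61 (SE 0.92, adjusted p = 0.0325), thrombospondin 4 (THBS4) by 4.54 (SE 0.80, adjusted p = 0.0199), fibronectin (FN1) by 1.98 (SE 0.37, adjusted p = 0.0271) and fibrillin (FBN1) by 1.61 (SE 0.34, adjusted p = 0.0366). The monocyte chemokine CCL2 rose by 2.27 (SE 0.44, adjusted p = 0.0303) and the antibacterial protein gene BPI by 2.55 (SE 0.46, adjusted p = 0.0223). MYLK, the smooth muscle myosin kinase (3.03-fold), TOP2A, a topoisomerase of dividing cells (1.46), PDPN (1.43) and the transcription cofactor LMO2 (1.38) rose too, as did skeletal actin, ACTA1, by 1.10 (SE 0.16, adjusted p = 0.00605). Genes that fell were LOC482182 (-2.13, SE 0.29, adjusted p = 0.00352), the cold-inducible RNA binding protein CIRBP (-1.18, SE 0.16, adjusted p = 0.00495) and the cardiac myosin kinase MYLK3 (-1.26, SE 0.22, adjusted p = 0.0213). Others were ACSBG1 (-1.37), LSMEM1 (-1.31), RAB9B (-1.27), SMTNL2 (-1.11), SNAP91 (-1.11), SCFD2 (-1.05) and the splicing factor SRSF5 (-1.01).

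Matrix and inflammatory lists were higher in RA early HF by camera. Of 52 genes of fibrillar collagen and matrix, 5 rose, 0 fell and 47 did not pass (31 higher and 1 lower adjusted over the list alone), led by THBS4, FN1, POSTN and FBN1; camera gave adjusted p = 9.94e-19, and adjusted p = 0.125 with an estimated correlation. Of 21 macrophage and myeloid markers, 0 passed over all probe sets and 16 were higher adjusted over the list alone, such as CTSS, a lysosomal protease (2.12, SE 0.48), MRC1 (0.71, SE 0.18) and C1QA (0.51, SE 0.13). The macrophage list passed camera as higher at adjusted p = 3.45e-15 (adjusted p = 0.125 with an estimated correlation). Of 20 fibroblast markers, 0 passed and 9 were higher adjusted over the list alone, with COL1A1 at 2.34 (SE 0.70), COL1A2 at 1.74 (SE 0.51), COL3A1 at 1.58 (SE 0.49) and PCOLCE at 0.63 (SE 0.18). The fibroblast list passed camera as higher at adjusted p = 4.46e-08 (adjusted p = 0.125 with an estimated correlation). Of 50 cytokine, chemokine and complement genes, CCL2 rose and 0 fell (9 higher adjusted over the list alone), with CXCL16 at 0.87 (SE 0.21) and C6 at 3.09 (SE 0.75). The cytokine list passed camera as higher at adjusted p = 3.4e-06 (adjusted p = 0.161 with an estimated correlation). Among 25 matrix proteases and inhibitors, 0 passed and 6 were higher adjusted over the list alone, including CTSK (1.40, SE 0.32) and TIMP1 (1.37, SE 0.35). The protease list passed camera as higher at adjusted p = 0.00323 (adjusted p = 0.125 with an estimated correlation). In the fit without the library labelled RA late 3, the matrix, macrophage, fibroblast, cytokine and protease lists had an adjusted p of 0.0468 with an estimated correlation. That fit had 21 matrix genes, 9 macrophage markers, 8 fibroblast markers, 9 cytokine genes and 6 proteases higher.

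Further lists were higher in RA early HF by camera. Of 25 cell cycle genes, TOP2A and DLGAP5 (0.59) rose and 0 fell (5 higher adjusted over the list alone). The cell cycle list passed camera as higher at adjusted p = 0.000595 (adjusted p = 0.254 with an estimated correlation). Of 19 endothelial markers, 0 passed and 3 were higher adjusted over the list alone: EMCN (0.80, SE 0.21), VWF (0.88, SE 0.26) and PECAM1 (0.76, SE 0.23). The endothelial list passed camera as higher at adjusted p = 0.00842 (adjusted p = 0.446 with an estimated correlation). Of 15 smooth muscle and pericyte markers, MYLK and RGS5 (1.05) rose and SMTN fell by 0.82 (3 higher and 1 lower adjusted over the list alone). The smooth muscle list passed camera as higher at adjusted p = 0.018 (adjusted p = 0.459 with an estimated correlation). Of 21 immediate early genes, IER3 rose (0.92) and 0 fell (3 higher adjusted over the list alone), with MCL1 at 0.98 (SE 0.26). The immediate early list passed camera as higher at adjusted p = 0.0194 (adjusted p = 0.459 with an estimated correlation). None of 29 interferon response genes passed, 0 adjusted over the list alone, with SAMD9L at 0.81 (SE 0.24) and B2M at 0.38 (SE 0.14). The interferon list passed camera as higher at adjusted p = 0.0371 (adjusted p = 0.583 with an estimated correlation). Single libraries ended some of these calls: for interferon response RA control 1 (adjusted p = 0.264 without it), RA control 2 (0.222), RA early 1 (0.193) and RA early 3 (0.208); for immediate early genes RA control 1 (adjusted p = 0.0611 without it), RA control 2 (0.222), RA early 1 (0.0691) and RA early 3 (0.0792). Others were for endothelial markers RA control 2 (adjusted p = 0.148 without it) and RA early 3 (0.0792), and for smooth muscle and pericyte markers RA control 3 (adjusted p = 0.1 without it) and RA early 1 (0.0923).

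Mitochondrial, fat and atrial lists were lower in RA early HF by camera. Of 61 genes of oxidative phosphorylation, 3 fell, 0 rose and 58 did not pass (26 lower adjusted over the list alone): the complex I genes NDUFS8 (-0.61, SE 0.12), NDUFS7 (-0.72, SE 0.15) and NDUFA13 (-0.41, SE 0.09). The list passed camera at adjusted p = 1.01e-17, with adjusted p = 0.125 with an estimated correlation. Of 40 fatty acid oxidation genes 0 passed (3 higher and 3 lower adjusted over the list alone), with ACADS at -0.53 (SE 0.13) and UCP2 at 0.72 (SE 0.19). The fatty acid list passed camera as lower at adjusted p = 0.0425 (adjusted p = 0.583 with an estimated correlation). Of 19 adipocyte markers, UCP1 fell by 0.59 and 0 rose (2 lower adjusted over the list alone), with SCD at -0.87 (SE 0.26). The adipocyte list passed camera as lower at adjusted p = 0.0164 (adjusted p = 0.496 with an estimated correlation). None of 13 atrial myocyte markers passed, 0 adjusted over the list alone, with NR2F1 at -0.42 (SE 0.16) and GJA5 at -0.43 (SE 0.17). The atrial list passed camera as lower at adjusted p = 0.0436 (adjusted p = 0.371 with an estimated correlation). Single libraries ended some of these calls: for fatty acid oxidation RA control 1 (adjusted p = 0.175 without it), RA control 2 (0.222), RA early 2 (0.115) and RA early 3 (0.208); for adipocyte markers RA control 2 (adjusted p = 0.0732 without it) and RA early 1 (0.219); for atrial myocyte markers RA control 3 (adjusted p = 0.152 without it) and RA early 1 (0.217). With 1 library left out the number of lists past the threshold, 14 with all arrays, was lowest without RA control 2, at 9.

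The other 18 lists did not pass camera in RA early HF. Their adjusted p was 0.158 for the stress and fetal gene programme and for the sarcomere, 0.909 for potassium channels, 0.702 for sodium, calcium and pacemaker channels, 0.27 for calcium handling and for glycolysis, 0.69 for gap junction and intercalated disc, and 0.437 for adrenergic signalling and for cardiac transcription factors. It was 0.163 for TGF-beta, BMP and Wnt signalling, 0.223 for endoplasmic reticulum stress, 0.177 for antioxidant genes, 0.894 for ribosomal proteins, 0.13 for lymphocyte and mast cell markers, 0.549 for mesothelial and for neural markers, 0.773 for blood cell markers and 0.556 for ventricular myocyte markers. Of the heart failure and ion channel genes none passed in RA early HF: MYL2 was at 3.46 (SE 0.87, adjusted p = 0.0699), the potassium channel subunit KCNIP2 at -1.57 (SE 0.43, adjusted p = 0.0944), the calcium release channel RYR2 at -0.83 (SE 0.24, adjusted p = 0.117) and NPPB at 2.31 (SE 1.29, adjusted p = 0.464). With the library labelled RA late 3 left out, MYL2, KCNIP2, RYR2, COL1A1 and COL3A1 passed, with adjusted p = 0.0126, 0.0463, 0.0272, 0.0267 and 0.0203. The calcium pump ATP2A2 was at -0.30, SLC8A1 at -0.37, KCND3 at -0.17, KCNH2 at 0.02, KCNQ1 at -0.10, KCNA5 at 0.18, CACNA1C at -0.05, GJA1 at 0.04, PLN at -0.07 and MYL7 at -0.17.

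In RA early HF 209 probe sets passed by limma, 79 higher and 130 lower. Array weights gave 1279 and a fit of these groups alone 724. Leaving out RA early 1 gave 17 higher and 193 lower. Quantile normalization gave 222 higher and 198 lower, and median-centring 33 higher and 94 lower. The count was 20 without RA early 3, 22 without RA control 2, 25 without RA control 1, 52 without RA control 3, 85 without RA early 2 and 829 without the library labelled RA late 3. With that library out it was 236 without RA control 2, 304 without RA early 3, 315 without RA control 1 and 394 without RA control 3. Of the 20 genes named for the size of their change, LOC482182 and CIRBP passed in every fit that left out a single array of these groups.

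**Figure D2:**
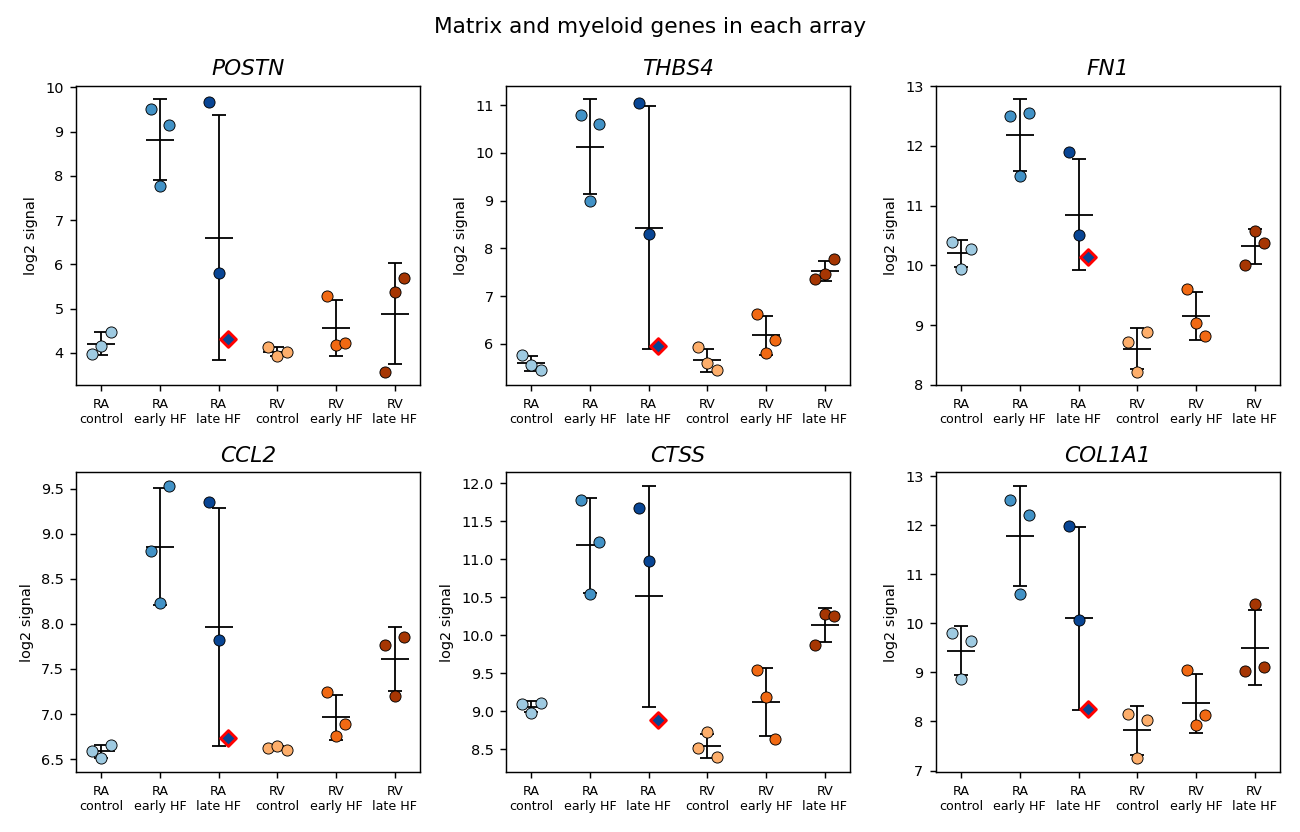
Log2 signal of matrix and myeloid genes in each array of the 6 groups; points are arrays, bars are group means with SD (n = 3), and the diamond with a red edge is the library labelled RA late 3. POSTN averaged 8.81 in RA early HF and 4.20 in RA controls.

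Late HF in the right atrium was compared with control in the same way. With all arrays, ACTA1 rose by 1.00 (SE 0.16, adjusted p = 0.0253) and SMYD2, a lysine methyltransferase, by 1.38 (SE 0.23, adjusted p = 0.0272). PAAF1, a proteasome assembly factor, was at -0.76 (SE 0.10, adjusted p = 0.00994) and the uncoupling protein UCP1 at -0.70 (SE 0.12, adjusted p = 0.036), both lower. The nearest genes that did not pass were CD36 (0.93, SE 0.18, adjusted p = 0.0597), MYL2 (4.61, SE 0.87, adjusted p = 0.0607), SAP30L (0.82, SE 0.16, adjusted p = 0.0609), ACSBG1 (-1.66, SE 0.30, adjusted p = 0.0541), RAB9B (-1.25, SE 0.23, adjusted p = 0.0541) and SLC35F6 (-0.46, SE 0.08, adjusted p = 0.0575). Without the library labelled RA late 3 (n = 2 in the late group), THBS4 rose by 4.09 (SE 0.57, adjusted p = 0.00813) and POSTN by at least 3.54 (SE 0.82, adjusted p = 0.0411). The MHC class II genes DLA-DQA1, DLA-DQB1 and DLA-DRA rose in that fit, by 2.82 (SE 0.44, adjusted p = 0.0126), 2.52 (SE 0.35, adjusted p = 0.0077) and 2.42 (SE 0.42, adjusted p = 0.0151). They rose in RA early HF in the same fit too, by 2.68 (SE 0.39, adjusted p = 0.0033), 1.96 (SE 0.31, adjusted p = 0.00416) and 2.37 (SE 0.37, adjusted p = 0.00416). The myeloid gene CLEC12A (3.02), LY96 (2.47), EPYC (2.30), CFI (2.29) and MYL2 (3.48) rose too. Lower without the library were ACSBG1 (-1.35), SMTNL2 (-0.94), SNAP91 (-0.93), RAB9B (-0.90), RYR2 (-0.88), VEGFA (-0.85), CA14 (-0.80), NEDD9 (-0.73), STRBP (-0.72) and PAAF1 (-0.72).

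Of the lists, 8 passed camera in RA late HF with all arrays. In the fit without the library labelled RA late 3, 3 others passed as higher. Ribosomal proteins had 0 of 50 genes past and 45 positive (camera adjusted p = 1.39e-06; adjusted p = 0.599 with an estimated correlation), and fibroblast markers 0 of 20 past and 10 adjusted over the list alone (0.000181 and 0.306). Antioxidant genes had 1 of 37 past (0.00608 and 0.307). With all arrays, none of 21 macrophage and myeloid markers passed alone, 0 adjusted over the list alone, with CTSS at 1.45 (SE 0.48) and LYZ at 1.12 (SE 0.38). The macrophage list passed camera as higher at adjusted p = 5.62e-06 (adjusted p = 0.765 with an estimated correlation). Of them 8 rose without the library labelled RA late 3, among them CTSS by 2.27 (SE 0.30) and LYZ by 1.70 (SE 0.28). None of 52 matrix genes passed, 0 adjusted over the list alone, with ASPN at 0.67 (SE 0.19) (camera adjusted p = 0.00628; adjusted p = 0.824 with an estimated correlation), and 4 rose without the library. None of 29 interferon response genes passed, 0 adjusted over the list alone, with SAMD9L at 0.87 (SE 0.24) and OAS1 at 0.35 (SE 0.12). The interferon list passed camera as higher at adjusted p = 0.000214 (adjusted p = 0.765 with an estimated correlation). None of 50 cytokine, chemokine and complement genes passed, 0 adjusted over the list alone, with CCL2 at 1.38 (SE 0.44) and CFI at 1.48 (SE 0.51). The cytokine list passed camera as higher at adjusted p = 0.022 (adjusted p = 0.795 with an estimated correlation). Of 61 oxidative phosphorylation genes 0 passed, also adjusted over the list alone, with NDUFS7 at -0.34 (SE 0.15) and SDHD at 0.31 (SE 0.09); the list was lower at camera adjusted p = 0.022 and adjusted p = 0.824 with an estimated correlation. Single libraries ended some of these calls: for fibrillar collagen and matrix RA control 2 (adjusted p = 0.0502 without it) and RA late 1 (0.853); for interferon response RA late 2 (adjusted p = 0.0813 without it); for cytokines, chemokines and complement RA control 2 (adjusted p = 0.0502 without it), RA late 1 (0.445) and RA late 2 (0.237). For oxidative phosphorylation these were RA control 1 (adjusted p = 0.148 without it), RA late 1 (0.295) and RA late 2 (0.381).

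Lists of chamber and fat markers passed camera in RA late HF as well. Of 19 adipocyte markers, UCP1 fell and 0 rose (3 lower adjusted over the list alone), with SCD at -1.13 (SE 0.26) and DGAT2 at -1.65 (SE 0.54). The adipocyte list passed camera as lower at adjusted p = 0.000107 (adjusted p = 0.765 with an estimated correlation). None of 13 atrial myocyte markers passed, 1 was lower adjusted over the list alone, with FGF12 at -0.45 (SE 0.13) and PAM at -1.20 (SE 0.42). The atrial list passed camera as lower at adjusted p = 0.00208 (adjusted p = 0.472 with an estimated correlation). None of 20 ventricular myocyte markers passed, 3 were higher adjusted over the list alone, with MYL2 and MYOZ2 (0.45, SE 0.09) in front. The ventricular list passed camera as higher at adjusted p = 0.00495 (adjusted p = 0.795 with an estimated correlation). Both chamber calls ended without the library labelled RA late 3, at adjusted p = 0.132 and 0.847. The list count of 8 was 5 without RA late 2.

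Of the heart failure and ion channel genes none passed in RA late HF with all arrays, and MYL2 and RYR2 did without the library labelled RA late 3. With all arrays and then without that library, NPPB was at 0.10 (SE 1.29) and 1.94 (SE 1.03), COL1A1 at 0.66 (SE 0.70) and 1.59 (SE 0.60), COL3A1 at 0.38 (SE 0.49) and 1.09 (SE 0.39), and KCNIP2 at -0.88 (SE 0.43) and -1.19 (SE 0.46). In the same order RYR2 was at -0.57 (SE 0.24) and -0.88 (SE 0.21) and MYL7 at -0.92 (SE 0.39) and -0.19 (SE 0.16). Smaller values were those of ATP2A2 (-0.27 and -0.37), SLC8A1 (-0.14 and -0.44), KCND3 (-0.16 and -0.25), KCNH2 (-0.03 and -0.10), KCNQ1 (-0.06 and -0.11), KCNA5 (0.14 and 0.12), CACNA1C (-0.14 and -0.25), GJA1 (0.08 and -0.11), GJA5 (-0.06 and 0.07) and PLN (-0.01 and -0.06).

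With all arrays 18 probe sets passed in RA late HF by limma, 8 higher and 10 lower. A fit of these groups alone gave 0, which ends the calls of ACTA1, SMYD2, PAAF1 and UCP1, while array weights gave 2578 and leaving out probe sets that may cross-hybridise 10. The count was 1 without RA control 1, 3 without RA late 1, 5 without RA control 2, 61 without RA late 2 and 425 (311 higher, 114 lower) without the library labelled RA late 3. With that library out it was 35 without RA control 1, 157 without RA control 2, 63 without RA control 3, 0 without RA late 1 and 3119 without RA late 2. These last 2 fits have 1 array in the late group, assumed to vary like the other groups. Of ACTA1, SMYD2, PAAF1 and UCP1, 0 passed in every fit that left out a single array of these groups.

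Early HF in the right ventricle was compared with control. Genes that rose included SORBS2, an adaptor of the intercalated disc (1.54, SE 0.24, adjusted p = 0.0159), the prostaglandin receptor PTGER4 (1.45, SE 0.21, adjusted p = 0.0124), ANTXR2 (1.44, SE 0.26, adjusted p = 0.0428) and ANKHD1 (1.36, SE 0.18, adjusted p = 0.0116). FHL1 rose with them by 1.10 (SE 0.20, adjusted p = 0.0497), the actin filament nucleator LMOD2 by 0.79 (SE 0.15, adjusted p = 0.0497) and the kinase ALPK2 by 0.97 (SE 0.17, adjusted p = 0.0337). YWHAQ (1.08), TSPAN2 (0.98) and USP28 (0.77) rose too. The neurofilament gene NEFL fell, with -3.86 (SE 0.53, adjusted p = 0.0116). MYOT, a sarcomeric Z-disc protein, rose by 2.38 (SE 0.47, adjusted p = 0.0304) without the library labelled RA late 3, and CTSK by 1.37 (SE 0.27, adjusted p = 0.03). CTH (1.88), ABRA (1.67), YLPM1 (1.55) and CYP1B1 (1.51) rose in that fit. Lower were LOC612108 (-1.90), SNAP91 (-1.04), FRMD3 (-0.90), GNB3 (-0.69), VEGFA (-0.67), MRPL12 (-0.67), SLC25A12 (-0.67) and MRPL48 (-0.66). The other probe sets of USP28 and FRMD3, and some of ANKHD1, did not share the direction.

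Muscle and stress lists were higher in RV early HF by camera. Of 18 genes of the stress and fetal programme, FHL1 rose and 0 fell (6 higher adjusted over the list alone), with MYOT at 2.38 (SE 0.51) and CSRP3 at 0.57 (SE 0.14). The fetal gene list passed camera as higher at adjusted p = 1.37e-08 (adjusted p = 0.122 with an estimated correlation). Of 27 genes of the gap junction and intercalated disc, SORBS2 rose and 0 fell (7 higher adjusted over the list alone), with CXADR at 0.75 (SE 0.15) and NRAP at 1.01 (SE 0.22). The intercalated disc list passed camera as higher at adjusted p = 1.08e-06 (adjusted p = 0.112 with an estimated correlation). Of 42 sarcomere genes, LMOD2 rose and 0 fell (8 higher adjusted over the list alone), with MYOM1 at 0.88 (SE 0.17) and NEBL at 1.10 (SE 0.29). The sarcomere list passed camera as higher at adjusted p = 1.68e-05 (adjusted p = 0.286 with an estimated correlation). None of 33 genes of endoplasmic reticulum and heat shock stress passed, 0 adjusted over the list alone, with PDIA4 at 0.95 (SE 0.30) and HSP90AA1 at 0.48 (SE 0.16). The heat shock list passed camera as higher at adjusted p = 1.82e-05 (adjusted p = 0.353 with an estimated correlation). None of 21 immediate early genes passed and 4 were higher adjusted over the list alone, with MCL1 at 1.25 (SE 0.26) and IER3 at 0.89 (SE 0.20). The immediate early list passed camera as higher at adjusted p = 0.000938 (adjusted p = 0.353 with an estimated correlation). Ribosomal protein genes stood beside these: 47 of 50 had a positive value, 0 passed, also adjusted over the list alone (RPLP0 0.30 (SE 0.12), RPL7 0.43 (SE 0.18)). The ribosomal list passed camera as higher at adjusted p = 1.43e-09 (adjusted p = 0.643 with an estimated correlation).

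The oxidative phosphorylation list was lower in RV early HF by camera, at adjusted p = 4e-21 (adjusted p = 0.125 with an estimated correlation). Of its 61 genes 0 passed and 22 were lower adjusted over the list alone, with NDUFAB1 at -0.40 (SE 0.08) and SDHB at -0.38 (SE 0.10). None of 52 matrix genes passed, 0 adjusted over the list alone, with DCN at 0.45 (SE 0.14) and CCN2 at 2.62 (SE 0.92); the list was higher at camera adjusted p = 0.000378 and adjusted p = 0.643 with an estimated correlation. None of 20 fibroblast markers passed, 0 adjusted over the list alone, with DCN and GSN (0.45, SE 0.18) in front. The fibroblast list passed camera as higher at adjusted p = 0.00521 (adjusted p = 0.623 with an estimated correlation). None of 27 potassium channel genes passed, 0 adjusted over the list alone, with KCNIP2 at -1.19 (SE 0.43) and KCNJ15 at -0.22 (SE 0.09). The potassium channel list passed camera as lower at adjusted p = 0.0421 (adjusted p = 0.643 with an estimated correlation). Single libraries ended some of these calls: for fibrillar collagen and matrix RV early 1 (adjusted p = 0.0539 without it); for potassium channels RV control 2 (adjusted p = 0.0695 without it), RV control 3 (0.228), RV early 1 (0.0803) and RV early 3 (0.0796).

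None of the heart failure and ion channel genes passed in RV early HF. NPPB was at 2.22 (SE 1.29), COL1A1 at 0.55 (SE 0.70), COL3A1 at 0.55 (SE 0.49), RYR2 at -0.39 (SE 0.24), ATP2A2 at -0.35 (SE 0.15) and KCNA5 at -0.23 (SE 0.10). The values of KCND3 (-0.14), KCNH2 (-0.03), KCNQ1 (0.02), CACNA1C (-0.15), GJA1 (-0.18), GJA5 (0.01), PLN (-0.01), SLC8A1 (0.08), MYL2 (0.19) and MYL7 (0.04) were small beside their errors or did not pass.

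By limma 27 probe sets passed in RV early HF, 24 higher and 3 lower. RV early libraries stood at 0.173, 0.115 and 0.113 on the axis of chamber markers. RV early 1 had 60% of the RV control level, on a scale from RA controls, as the median of 16 genes higher in RV controls. The controls define both, so a shift from them was not tested. Array weights gave 384, leaving out the lowest 60% of signals 66, a prior without trend 41 and leaving out probe sets that may cross-hybridise 11. Quantile normalization gave 48 higher and 14 lower. The count was 0 without RV control 2, RV control 3 or RV early 3, 6 without RV control 1, 8 without RV early 1, 306 without RV early 2 and 139 (96 higher, 43 lower) without the library labelled RA late 3. With that library out it was 34 without RV control 1, 9 without RV control 2, 50 without RV control 3, 22 without RV early 1, 459 without RV early 2 and 29 without RV early 3. Of the 11 genes named for the size of their change, 0 passed in every fit that left out a single array of these groups.

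Late HF in the right ventricle gave no probe set past the threshold with all arrays. The nearest genes, all at an adjusted p of 0.386, were FN1 (1.71, SE 0.37), LMO2 (1.27, SE 0.29), PDLIM1 (0.60, SE 0.14), the macrophage gene F13A1 (1.09, SE 0.25) and FAM13C (0.50, SE 0.12) among positive values. Among negative ones they were TAMM41 (-0.43, SE 0.08), SNAP91 (-1.03, SE 0.21), UBE2C (-0.59, SE 0.12), PUS3 (-0.47, SE 0.10) and WDR81 (-0.45, SE 0.10). Without the library labelled RA late 3, the matrix gene EFEMP1 rose by 1.65 (SE 0.30, adjusted p = 0.0437), ABI3BP by 1.61 (SE 0.26, adjusted p = 0.0264), the lysosomal protease CTSS by 1.59 (SE 0.27, adjusted p = 0.0267), KERA by 1.28 (SE 0.18, adjusted p = 0.0117) and lumican (LUM) by 1.15 (SE 0.19, adjusted p = 0.0264). CYP1B1 (1.55), HNMT (1.28), LMO2 (1.27), BTG3 (1.21), VIM (0.92) and the atrial light chain MYL7 (0.82) rose in that fit. SNAP91 (-1.03), CAMK2B (-0.88), OLFM1 (-0.83) and UBE2C (-0.59) were lower. The RV late libraries stood at 0.345, 0.244 and 0.266 on the axis of chamber markers, which the controls define, so a shift was not tested. RV late 1 had MYL2 at 12.76, MYL3 at 12.35 and 41.3% on the scale of the 16 ventricular genes.

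Lists of matrix and inflammation were higher in RV late HF by camera, while 0 of their genes passed alone. Of 52 matrix genes 6 were higher adjusted over the list alone, with FN1, DCN (0.59, SE 0.14), LUM (1.15, SE 0.31) and FBN1 (1.22, SE 0.34) in front. The matrix list passed camera as higher at adjusted p = 2.21e-12 (adjusted p = 0.295 with an estimated correlation). Of 20 fibroblast markers 7 were higher adjusted over the list alone, with VIM at 0.92 (SE 0.23) and GSN at 0.63 (SE 0.18). The fibroblast list passed camera as higher at adjusted p = 9.79e-07 (adjusted p = 0.291 with an estimated correlation). Of 21 macrophage and myeloid markers 2 were higher adjusted over the list alone, with F13A1 and CTSS (1.59, SE 0.48) in front. The macrophage list passed camera as higher at adjusted p = 9.79e-07 (adjusted p = 0.406 with an estimated correlation). Of 25 matrix proteases and inhibitors 1 was higher adjusted over the list alone, with CTSK at 1.37 (SE 0.32) and TIMP3 at 0.63 (SE 0.23). The protease list passed camera as higher at adjusted p = 0.000136 (adjusted p = 0.134 with an estimated correlation). None of 50 cytokine, chemokine and complement genes was past adjusted over the list alone, with C1S at 1.37 (SE 0.45) and CFI at 1.38 (SE 0.51). The cytokine list passed camera as higher at adjusted p = 0.000589 (adjusted p = 0.406 with an estimated correlation). None of 29 interferon response genes was past adjusted over the list alone, with OAS1 at 0.43 (SE 0.12) and IFI35 at 0.26 (SE 0.12). The interferon list passed camera as higher at adjusted p = 0.00105 (0.472 with an estimated correlation), but not without RV late 3 (0.166). In the fit without the library labelled RA late 3, the protease and fibroblast lists had an adjusted p of 0.0419 with an estimated correlation.

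The remaining lists that passed camera in RV late HF also had 0 genes past over all probe sets. Of 18 stress and fetal genes 1 was higher adjusted over the list alone, FHL1 at 0.79 (SE 0.20), with UCHL1 at 1.33 (SE 0.53). The fetal gene list passed camera as higher at adjusted p = 0.00345 (adjusted p = 0.406 with an estimated correlation). Adjusted over the list alone, 0 of 37 antioxidant genes passed, with MAOB at 0.70 (SE 0.24) and PRDX1 at 0.39 (SE 0.15). The antioxidant list passed camera as higher at adjusted p = 0.000556 (adjusted p = 0.291 with an estimated correlation). For 27 genes of the gap junction and intercalated disc it was 0, with CAV1 at 0.52 (SE 0.18) and CTNNB1 at 0.38 (SE 0.14). The intercalated disc list passed camera as higher at adjusted p = 0.00594 (adjusted p = 0.368 with an estimated correlation). For 15 smooth muscle and pericyte markers it was 0, with CALD1 at 0.76 (SE 0.23) and RGS5 at 0.38 (SE 0.21). The smooth muscle list passed camera as higher at adjusted p = 0.0395 (adjusted p = 0.524 with an estimated correlation). For 19 adipocyte markers it was 0, with RBP4 at 2.34 (SE 0.70) and FABP4 at 1.43 (SE 0.66). The adipocyte list passed camera as higher at adjusted p = 0.00126 (adjusted p = 0.406 with an estimated correlation). For 50 ribosomal protein genes it was 0, while 46 had a positive value (RPL26 0.34 (SE 0.11), RPL17 0.60 (SE 0.21)). The ribosomal list passed camera as higher at adjusted p = 1.06e-11 (adjusted p = 0.472 with an estimated correlation). For 61 oxidative phosphorylation genes it was 0, with NDUFAB1 at -0.21 (SE 0.08) and NDUFC2 at -0.22 (SE 0.09); that list was lower. The oxidative phosphorylation list passed camera as lower at adjusted p = 0.00135 (adjusted p = 0.602 with an estimated correlation). Single libraries ended some of these calls: for oxidative phosphorylation RV control 1 (adjusted p = 0.0598 without it); for smooth muscle and pericyte markers RV control 2 (adjusted p = 0.323 without it), RV control 3 (0.288), RV late 1 (0.0669) and RV late 3 (0.413).

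By limma 0 probe sets passed in RV late HF with all arrays, 2372 had an unadjusted p under 0.05, and the smallest adjusted p was 0.262. A fit of these groups alone gave 257, 207 higher and 50 lower, and array weights gave 229. Without the library labelled RA late 3, which is no array of this comparison and enters through the shared spread, 34 passed, 22 higher and 12 lower. With that library out the count was 18 without RV control 1, 1 without RV control 2, 6 without RV control 3 and 3 without RV late 3. Of the heart failure and ion channel genes, none passed with all arrays: NPPB was at 1.53 (SE 1.29), COL1A1 at 1.69 (SE 0.70), COL3A1 at 1.13 (SE 0.49), KCNIP2 at -1.36 (SE 0.43), KCNA5 at -0.28 (SE 0.10), GJA5 at 0.42 (SE 0.17) and MYL7 at 0.82 (SE 0.39). KCND3 (-0.20), KCNH2 (0.07), KCNQ1 (-0.08), CACNA1C (-0.15), GJA1 (-0.11), RYR2 (-0.38), ATP2A2 (-0.24), PLN (0.13), SLC8A1 (-0.22) and MYL2 (-0.36) had the values given.

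The stages were also compared with each other within each chamber. Of the genes named for HF against control, POSTN differed in RA by -2.21 (SE 0.92, adjusted p = 0.559) and THBS4 by -1.70 (SE 0.80, adjusted p = 0.618) between late and early HF, neither past the threshold. In the fit without the library labelled RA late 3 they differed by -1.07 (SE 0.82, adjusted p = 0.717) and -0.46 (SE 0.57, adjusted p = 0.838). In RV, FN1 differed by 1.17 (SE 0.37, adjusted p = 0.702) and NEFL by 2.09 (SE 0.53, adjusted p = 0.483), which did not pass either. By limma 0 probe sets passed in RA, with 2068 at an unadjusted p under 0.05 and a smallest adjusted p of 0.212, and 0 passed in RV, with 1433 and 0.272. Array weights gave 2479 in RA and 3 in RV. In RA the count was 88 without RA late 1, 1 without RA early 2 and 1 without RA early 3; in RV it was 72 without RV early 2. Both counts were 0 without the library labelled RA late 3 (2236 and 1844 at an unadjusted p under 0.05), and then 16 in RA without RA late 2, with 1 array left in the late group, and 121 in RV without RV early 2.

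The difference between the chambers in the HF effect was tested directly. For early HF 1 probe set passed. It has no gene symbol, and RV controls lay near background. Its RA effect was -0.96, its RV effect 0.12 and the difference -1.08 (SE 0.14, adjusted p = 0.0258). It passed for late HF as well, with a difference of -1.11 (adjusted p = 0.0188). Another without a gene symbol passed for late HF, with 2.46 (SE 0.36, adjusted p = 0.0376; RA effect 0.89, or 0.565 without the library labelled RA late 3, RV effect -1.57). No gene with a symbol passed. Of the genes named for early HF, POSTN had a difference of 4.08 (SE 1.30, adjusted p = 0.702) for early HF, THBS4 4.03 (SE 1.12, adjusted p = 0.628), FN1 1.44 (SE 0.53, adjusted p = 0.753), SORBS2 -0.94 (SE 0.33, adjusted p = 0.74) and NEFL 4.06 (SE 0.76, adjusted p = 0.226). A change past the threshold in one chamber alone is therefore not shown to differ between the chambers for these genes. With the chambers paired by number, 0 probe sets passed for early and 0 for late HF, as when the lowest 60% of signals were left out. Array weights gave 13 and 18, and fits of the compared groups alone 10 and 0. The early count of 1 became 0 without RA control 2, RV early 1 or 3, or any single RA early or RV control array. It was 4 without RA control 3 and 12 without RV early 2. For late HF the count of 2 became 0 without RV control 1, RV control 2, RV control 3 or RV late 2, 1 without RA control 1 or RV late 3, 4 without RA control 3 and 5 without RA late 2, and with quantile normalization 0 were higher and 1 lower in place of 1 and 1.

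Lists were tested for a difference between the chambers as well. With an estimated correlation 0 lists passed at either stage. For early HF 14 lists passed camera. As a list, macrophage and myeloid markers leaned to a higher effect in RA, with 0 of 21 past alone and 0 adjusted over the list alone (CTSS 1.54 (SE 0.68), CD86 1.08 (SE 0.44)). The macrophage list passed camera as higher at adjusted p = 4.61e-09 (adjusted p = 0.282 with an estimated correlation). Matrix genes as a list also leaned to a higher effect in RA, with 0 of 52 past and 0 adjusted over the list alone (POSTN, THBS4). The matrix list passed camera as higher at adjusted p = 4.3e-08 (adjusted p = 0.315 with an estimated correlation). Sarcomere genes had the higher effect in RV, with 0 of 42 past and 1 lower adjusted over the list alone (MYOM1 -1.09 (SE 0.23), MYOZ1 -1.69 (SE 0.49)). The sarcomere list passed camera as lower at adjusted p = 4.55e-07 (adjusted p = 0.268 with an estimated correlation). Ribosomal protein genes also had the higher effect in RV, with 0 of 50 past and 0 adjusted over the list alone (RPS28 -0.34 (SE 0.14)). The ribosomal list passed camera as lower at adjusted p = 2.92e-06 (adjusted p = 0.591 with an estimated correlation). Atrial myocyte markers passed as lower in RA only without the library labelled RA late 3 (adjusted p = 0.0094, against 0.0559 with all arrays; adjusted p = 0.134 with an estimated correlation). For late HF 7 lists passed. Only the adipocyte and atrial lists of these passed without the library labelled RA late 3. Macrophage and endothelial markers then passed as higher in RA (adjusted p = 0.012 and 0.0254, but 0.897 and 0.877 with an estimated correlation). Adipocyte markers had the lower effect in RA, with 0 of 19 past and 7 lower adjusted over the list alone (SCD -1.39 (SE 0.37), RBP4 -3.68 (SE 0.99); camera adjusted p = 1.92e-08, adjusted p = 0.198 with an estimated correlation), and at adjusted p = 7.73e-08 without that library.

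Changes at the stages and in the chambers were set side by side over 10988 genes, which are not independent replicates. Early and late changes in RA correlated at 0.715 with all arrays and at 0.785 without the library labelled RA late 3; the controls they share alone gave 0.502 and 0.448 in simulation. In RV the correlation was 0.664 against 0.504 simulated. The 3 controls of a chamber are too few to give each stage its own, so shared controls are part of these values. The chambers share no array, but arrays of the same number correlated positively in controls and early HF, so independence cannot be taken as given. Between the chambers early changes correlated at 0.432 and late changes at 0.247, or 0.511 without the library labelled RA late 3.

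**Figure D3:**
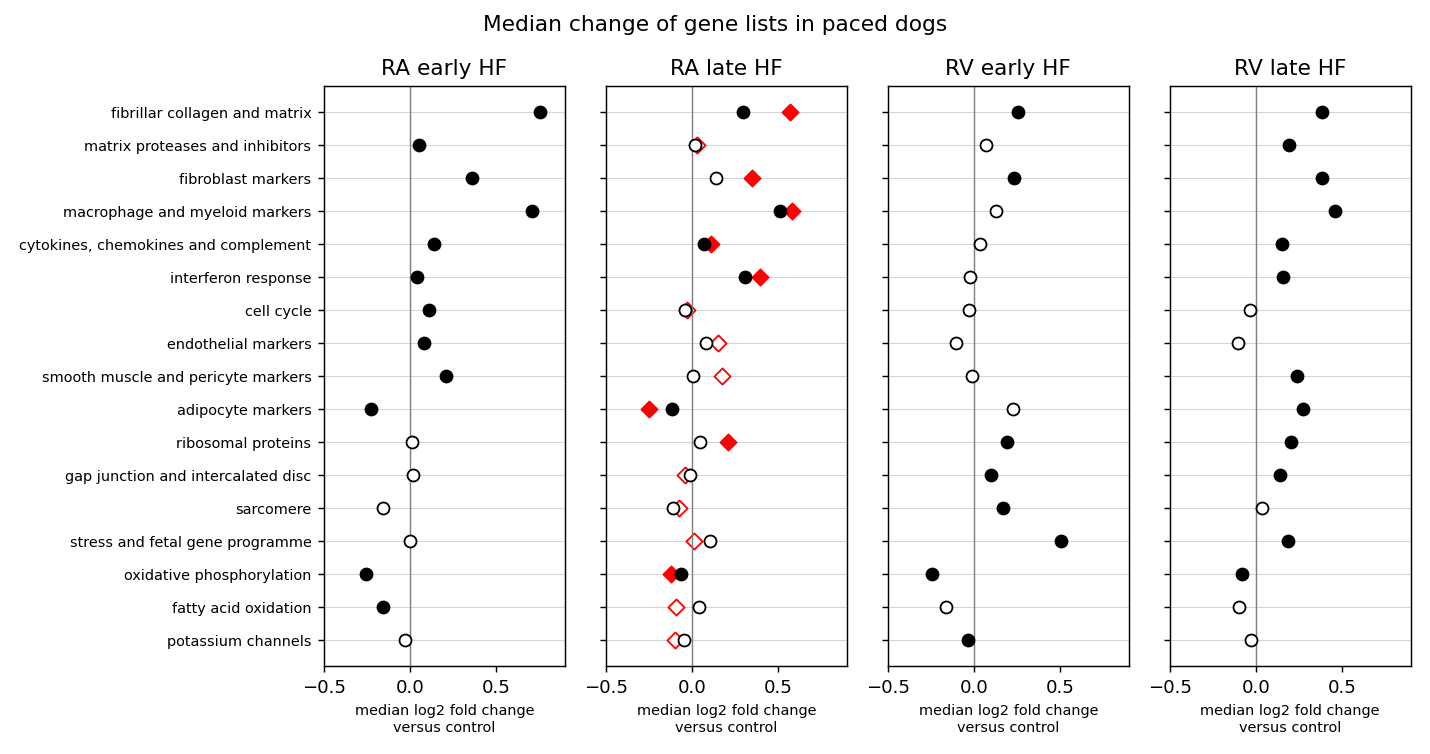
Median log2 fold change of 17 gene lists for each HF stage and chamber against control; filled points passed camera at an adjusted p under 0.05, open points did not, and red diamonds in the RA late panel leave out the library labelled RA late 3. Oxidative phosphorylation has a median of -0.26 in RA early HF and -0.25 in RV early HF.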

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

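The tests of explanations in this part were all chosen after the results were seen; the tests of differences between the chambers were planned.

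The library labelled RA late 3 had ventricular levels of chamber markers. A swap with an RV library of the series is argued against, since the RV library nearest to the atrium stood at 0.345 on the axis from RV control (0) to RA control (1), below the middle. An effect of late HF on the atrium is argued against as well, since the other RA late libraries stood at 0.958 or above. Ventricular tissue in the library had the values it needs: over 16 genes at least 4-fold higher in RV controls, the median ventricular share was 107% (quartiles 82.4 to 118), while the median atrial share over 27 genes was 4.87% (GJA5 76.3%). A wrong label, a sample from outside the series and a sampling of ventricle with some atrium may each account for this, and the values do not tell them apart.

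The list of macrophage and myeloid markers was higher in RA early HF by camera, with 0 of 21 past the threshold alone and adjusted p = 0.125 with an estimated correlation. A lower share of myocytes would raise the markers of every other cell type alike. In the RA early libraries the macrophage medians were 1.13, 0.42 and 0.72 above the control mean and the endothelial medians 0.06, 0.07 and 0.24, and the smallest difference between them was 0.347, against an SD of 0.155 in controls. This argues against a lower myocyte share as the whole cause. An entry of macrophages with early HF and a change within cells already there may each account for it, and no test here parts them.

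MYL2 was higher in the RA libraries of paced dogs, by 3.46 in early HF and 3.48 in late HF without the library labelled RA late 3. Ventricular tissue carried into these libraries would bring the other abundant ventricular genes, MYL3 and FHL2, at the same share, which MYL2 puts between 3.82% and 22.8% in 5 arrays. Their shortfall below the needed level ran from -0.176 to 2.20 on the log2 scale. MYL3 lay between 0.53 and 1.76 below it in every array, FHL2 reached it in RA late 2, and the median share over the 16 ventricular genes (2.47, 5.11, 1.47, 0.955 and 6.82%) lay below the MYL2 share (3.82, 22.8, 7.31, 10.4 and 7.66%) in each. Carry-over and a change of MYL2 within the atrium therefore cannot be told apart, since FHL2 averages 10.38 in RA controls and the quartiles over the 16 genes hold the MYL2 share in all but RA early 2.

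The test of chamber differences picked out 1 probe set without a gene symbol, with -1.08 for early and -1.107 for late HF. RA controls had 6.18, 6.36 and 6.59 and the other groups between 5.23 and 5.64. RV controls (5.32, 5.37 and 5.23) lay near the background limit of 5.31, so a floor effect in RV is not excluded. For late HF the test also picked out another, with 2.46 and the effects given above.

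The same test by camera gave these adjusted p for the early HF effect, higher in RA: fibrillar collagen and matrix 4.3e-08, macrophage and myeloid markers 4.61e-09, endothelial markers 1.85e-05, cell cycle 4.86e-05, cytokines, chemokines and complement 0.000479, smooth muscle and pericyte markers 0.00241, fibroblast markers 0.00566 and interferon response 0.0148. Lower in RA were sarcomere 4.55e-07, gap junction and intercalated disc 2.92e-06, ribosomal proteins 2.92e-06, adipocyte markers 3.12e-05, the stress and fetal gene programme 0.00205 and endoplasmic reticulum and heat shock stress 0.043. With an estimated correlation these 14 lists had an adjusted p between 0.149 and 0.596. The calls that a single library ended were the stress and fetal list without RV early 1 (0.0619), the fibroblast list without RA early 1 (0.109) and the smooth muscle list without RV control 1 (0.19). The interferon call ended without RA control 1 (0.163), RA control 2 (0.116), RV control 3 (0.216), RA early 1 (0.12) or RA early 3 (0.116). The heat shock call ended without RA control 2 (0.111), RA control 3 (0.116), RV control 2 (0.246), RA early 2 (0.182), RA early 3 (0.264) or RV early 1 (0.599).

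For the late HF effect the test gave 1.92e-08 for adipocyte markers, 1.56e-05 for ribosomal proteins, 0.00172 for atrial myocyte markers, 0.00627 for fibrillar collagen and matrix and 0.00856 for fibroblast markers, all lower in RA. Ventricular myocyte markers (0.0221) and fatty acid oxidation (0.0252) were higher in RA. With an estimated correlation these 7 lists had an adjusted p between 0.198 and 0.939. Without the library labelled RA late 3 the adjusted p was 7.73e-08 for adipocyte, 0.00275 for atrial, 0.707 for collagen, 0.571 for fatty acid oxidation, 0.451 for ribosomal, 0.333 for fibroblast and 0.703 for ventricular lists, while macrophage (0.012) and endothelial markers (0.0254) passed as higher in RA (adjusted p = 0.897 and 0.877 with an estimated correlation). Fatty acid oxidation also lost its call without RA control 3 (0.307), RV control 1 (0.219) or RV late 1 (0.0727), and ventricular markers without RV late 1 (0.069).

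The 6 arrays of a comparison of 2 groups can be split in 10 ways, too few for a share under 0.05. As many probe sets as the real split came from 1 of 10 splits, the real one itself, for RA early HF (209, highest other 1), RA late HF (18, highest other 1), RV early HF (27, highest other 0) and RA against RV in controls (748, highest other 0). For RV late HF (0, highest other 4), RA late against early HF (0, highest other 415) and RV late against early HF (0, highest other 1), the real count is 0, so 10 of 10 splits reach it whatever the data and nothing was tested. The split of RA early 1, RA early 3 and RA late 1 against RA early 2, RA late 2 and the library labelled RA late 3 gave the 415, which points to a structure of these samples other than the stage. For the chamber difference in early HF, 16 of 100 splits gave 1 or more (highest other 2), so chance is not excluded. The splits relabel RA and RV arrays without regard to any pairing by number. For late HF 4 of 100 gave 2 or more, under a share of 0.05, but a split that left the RV groups as they are and set the library labelled RA late 3 with RA controls 1 and 2 gave 107, which points again to a structure of the samples.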

How the results depend on the processing

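No named gene, and no list called against control or between control chambers, that was past the threshold in the fit of all arrays passed it in the other direction under an alternative. Results not past it did turn: without the library labelled RA late 3, GJA5 in RA late HF went from -0.06 to 0.07, and macrophage markers for the late chamber difference from lower (adjusted p = 0.996) to higher (0.012, but adjusted p = 0.897 with an estimated correlation). The balance of higher and lower probe sets also turned, from 79 and 130 in RA early HF to 222 and 198 with quantile normalization, 179 and 151 with the number as a block, 420 and 409 without that library, 410 and 314 with the compared groups alone, 634 and 380 with an unadjusted p and 52 and 33 without RA early 2. With that library out it was 207 and 621 without RA early 1 and 507 and 212 without RA early 2. It went from 8 and 10 to 311 and 114 in RA late HF without that library. The fits without the library labelled RA late 3, without RA late 1 and 3, and further leave-outs beside the former were chosen after seeing the data; the others were planned. Adding an offset before the log was not run, since the values were deposited on a log scale. Leaving out RA late 1 and 3, or RA late 1 or 2 beside the library labelled RA late 3, leaves 1 array, assumed to vary like the other groups. Signal over background limits the dim genes: raising the filter or setting low values to a floor changes which are tested or flattened. Where a cause is not shown by the construction, the cause was not tested.

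Quantile normalization gave 420 probe sets in RA early HF, 62 in RV early HF and 1 for the late chamber difference; median-centring gave 127 in RA early HF. Leaving out the lowest 60% (fewer probe sets tested) gave 66 in RV early HF, 0 for the early and 0 for the late chamber difference. Without probe sets that may cross-hybridise (fewer tested) there were 10 in RA late HF, 11 in RV early HF and 494 in controls. A variance prior without trend gave 41 in RV early HF. Array weights gave 1279 in RA early, 2578 in RA late, 384 in RV early and 229 in RV late HF, 2479 for RA and 3 for RV late against early, 2605 in controls, and 13 and 18 for the early and late chamber differences.

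The number as a block gave 330 in RA early and 70 in RV early HF. Pairing the chambers by condition and number as a replicate block gave 0 for the early and 0 for the late chamber difference, and 963 in controls. In controls it ended the calls of RBP4 and of the intercalated disc list, brought NPPB past the threshold and changed no other call of a gene or list named there. The lists past the threshold numbered 10 in controls, where 1 other list passed, 15 for the early and 9 for the late chamber difference. Fits of the compared groups alone gave 724 in RA early, 0 in RA late and 257 in RV late HF, 2162 in controls, 10 for the early and 0 for the late chamber difference. Without the library labelled RA late 3 there were 829, 425, 139 and 34 in RA early, RA late, RV early and RV late HF and 1458 in controls; without RA late 1 and 3 there were 0 in RA late HF and 0 for the late chamber difference. An unadjusted p under 0.05 with 1.5-fold gave 1014, 568, 555 and 413 in RA early, RA late, RV early and RV late HF, 262 and 278 for RA and RV late against early, 1270 in controls, and 630 and 566 for the chamber differences. An adjusted p of 0.10 gave 630 in RA early, 45 in RA late and 130 in RV early HF and 1370 in controls.

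Leaving out 1 array of the groups compared gave 20 to 210 in RA early, 1 to 425 in RA late, 0 to 306 in RV early and 0 to 0 in RV late HF. It gave 0 to 88 for RA and 0 to 72 for RV late against early HF, 251 to 439 in controls, and 0 to 12 and 0 to 5 for the early and late chamber differences. The number of gene lists past the threshold ran from 9 to 13 in RA early, 5 to 9 in RA late, 9 to 14 in RV early and 11 to 16 in RV late HF, 8 to 11 in controls, 13 to 16 for the early and 4 to 9 for the late chamber difference.

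With an estimated correlation 0 lists passed in RA early, RA late, RV early and RV late HF and for the early and late chamber differences, and 1 in controls. The directional fry test gave 5 in RA early, 0 in RA late, 3 in RV early and 0 in RV late HF, 3 in controls, and 0 and 0 for the early and late chamber differences. The mixed fry test gave 0 in RA late HF, 0 in RV late HF and 24 in controls. It gave 2 for the early and 0 for the late chamber difference. Without the library labelled RA late 3, 4 lists passed for the late chamber difference.

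Calls of 202 results on genes stayed on their side of the threshold in 136 cases without the library labelled RA late 3 (66 passed newly), 128 with array weights (74 passed newly), 193 with quantile normalization (9 passed newly), 192 with median-centring (10 lost), 202 with the floor, 198 without a filter (4 lost), 196 with the robust prior (6 lost) 199 without trend (3 passed newly) and 156 with the compared groups alone (12 lost, 34 passed newly). Leaving out single arrays lost 41 of them in at least 1 fit. Of the list calls against control and between control chambers, 54 were lost and 1 was kept with an estimated correlation. The directional fry test lost 44 and kept 11. Leaving out single arrays lost 20 and kept 35, and quantile normalization lost 6 and kept 49. The mean of all probe sets of a gene lost 4 and kept 51. Without the library labelled RA late 3, 3 were lost and 52 kept. List calls for chamber differences are not included.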

Other observations

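The genes in this part were chosen after their values were seen, as those past the threshold in both chambers in the fits without the library labelled RA late 3. In early HF 8 genes rose in both chambers, where 0.684 would be expected from the counts if the chambers were independent. The chambers pair by number in controls and early HF and share each gene's fitted variance, so they are not independent. This holds for the other expected numbers between them. With all 18 arrays 0 genes passed in both chambers at either stage. The collagen-degrading protease CTSK rose by 1.40 in RA (SE 0.27, adjusted p = 0.0105) and 1.37 in RV (SE 0.27, adjusted p = 0.03), and the cross-linking enzyme TGM2 by 1.11 (SE 0.24, adjusted p = 0.0203) and 1.19 (SE 0.24, adjusted p = 0.0369). CYP1B1 (0.94 and 1.51), FAR2 (0.99 and 0.99), IER3 (0.92 and 0.89), the proteoglycan KERA (1.07 and 0.97), the survival factor MCL1 (0.98 and 1.25) and PTGER4 (0.89 and 1.45) rose in RA and RV in that order. Another 8 genes fell in both, where 0.22 would be expected: the mitochondrial genes SDHB (-0.33 and -0.38), NDUFAB1 (-0.31 and -0.40), IDH3B (-0.68 and -0.59) and MRPL48 (-0.66 and -0.66), and VEGFA (-0.49 and -0.67), CDK5RAP1 (-0.58 and -0.65) and SNAP91 (-1.11 and -1.04), beside PAAF1 (adjusted p = 0.000847 in RA and 0.0427 in RV).

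In late HF 4 genes rose in both chambers, where 0.135 would be expected: CTSS (2.27 in RA and 1.59 in RV), KERA (1.22 and 1.28), LMO2 (1.17 and 1.27) and BTG3 (0.82 and 1.21). SNAP91, a gene of clathrin coat assembly, fell in both (-0.93 and -1.03), where 0.00874 would be expected. Within RA, 69 genes were higher at both stages and 14 lower at both, where 1.86 and 0.33 would be expected, and within RV 3 and 1, where 0.0497 and 0.00582 would be expected. With all 18 arrays these numbers were 1 and 2 within RA and 0 and 0 within RV. The stages share their controls and variance, so chance alone would give more than the expected numbers.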
